A study of Mus musculus with 8 samples.

How the data were processed

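The series holds 8 RNA sequencing libraries of male mouse placentas from gestational day 16.5, 4 from control sires and 4 from alcohol-exposed sires. Each sample was placed in its group by the treatment label. Per the labels' protocols, total RNA was extracted from divided, frozen placentas, and libraries followed standard Illumina protocols. The authors deposited 1 table per library with whole-number counts per gene symbol, not normalized. Per the submitters' processing notes, Trimmomatic, STAR, featureCounts and DESeq2 were used and the genome build was mm39. Tool versions, the annotation, the strand setting, the counting of mates and the handling of duplicates and of reads with several alignments are not given in the sources used here. Among counts of 1 to 50, the share of even values was 71.7% to 88.8% per library, as would follow if both mates of most pairs had been counted, and a halving of every count was tried for that reason. Columns not mapped to a sample numbered 0.

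The tables list 53819 genes, of which 39116 had a count in some library. Ribosomal RNA genes (mt-Rnr2, Rn18s and mt-Rnr1) held 78.5% to 96.4% of a library's counts and were kept in library sizes, so that CPM values are low. Because the non-ribosomal depth was 2.97 to 14.2 M counts (M, mega), low genes were measured with much less precision in some libraries than in others. Intervals cover the spread between libraries, and reads without molecular identifiers are not independent molecules. Libraries were compared in pairs. Spearman correlations over tested genes ran from 0.882 to 0.977, and the lowest chi-square per degree of freedom was 14.2, so no pair differed by as little as sampling noise and each library counted as 1 replicate.

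Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr by group, which left 14120 genes, libraries were scaled by TMM, with factors from 0.25 to 2.00, and edgeR's quasi-likelihood test was fitted with the sire group as the only term, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The common biological coefficient of variation was 36.5%. Log2 CPM values used a prior count of 2, which understates differences of low genes. Gene lists with at least 5 tested genes went through limma's camera with a preset correlation of 0.01, beside camera with an estimated correlation, fry (which asks whether a set's genes move on balance in 1 direction) and an exact two-sided permutation of the list mean. The 34 lists cover placental cell types and layers (spongiotrophoblast, pregnancy-specific glycoproteins, prolactin family, glycogen trophoblast, giant cells with cathepsins, labyrinth syncytiotrophoblast, fetal endothelium, stroma and pericytes, decidua, uterine natural killer cells, macrophages, neutrophils, erythroid cells and yolk sac), imprinted genes of either parental expression, nutrient transporters, and pathways from hypoxia, respiration, ribosomal proteins, antioxidant and stress responses to sterols, fatty acids, interferon, proliferation, growth factors, alcohol metabolism, chromatin, steroids, immediate early genes, the clock and nuclear-retained RNA. The spread between libraries was the median over genes with a mean log2 CPM of at least 1 of log2(SD with an alcohol-exposed sire / SD with a control sire).

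Groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names up to 12 genes per direction with the largest change among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups. A direction with fewer than 6 is filled up to 6 with the genes of lowest unadjusted p at that expression, leaving out predicted genes and pseudogenes, given as values. The rule adds up to 4 members past the threshold of each list that passed camera, or else its 2 members of lowest p as values, up to 2 members past the threshold of each other list, and the panel Igf2, H19, Cdkn1c, Phlda2, Grb10, Peg10, Tpbpa, Prl3b1, Pcdh12, Slc2a1, Hsd11b2 and Flt1. Other genes appear only as examples of their list.

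The alternatives were size factors by median of ratios, upper quartile scaling, total counts alone, no filter, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom with quality weights, the likelihood ratio test, each library left out in turn, haemoglobin and mitochondrial genes left out, the decidua score or the layer score as a covariate, and 1 surrogate variable from sva 3.50.0. Added after the data had been seen were the ribosomal RNA genes left out, counts halved, all libraries thinned to 2973380 non-ribosomal counts, 2 libraries left out together, and loess trends on transcript length or GC share removed. Length and GC came from the longest GENCODE M21 transcript of each gene symbol, which need not be the one expressed. The genome build of that release differs from that of the counts, so no coordinates are given. A value was found for 97.8% of tested genes. The labels give no batch, dam or shared replicate number, so no block was fitted. Figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

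The steps were tested on simulated data for the comparison of alcohol-exposed against control sires. Changes were planted only in genes with a mean log2 CPM of at least 1, reached by 6809 of the 14120 tested genes. Power for lower genes was not measured. The 200 changes were planted together, which eases the Benjamini-Hochberg threshold, so the shares called do not hold for only a few changed genes. With counts drawn for 13813 tested genes, 23 of 100 genes changed 2-fold and 96 of 100 changed 4-fold were called, and 5 unchanged genes were called. With changes planted in the real libraries, over 14120 genes, 41 of 100 at 2-fold and 92 of 100 at 4-fold were called, and 1 unchanged gene was. Simulated counts with no change gave 1 gene and 0 lists past the threshold. Each gene was drawn independently there, so the 0 does not test camera on lists whose genes vary together. A list shifted by 0.5 was recovered at 0.39 on the log2 CPM scale.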

Results

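Total RNA was sequenced from 8 mouse placentas collected on gestational day 16.5, all from male fetuses of the cross labelled C57BL/6J x CD-1. In 4 placentas the sire had drunk alcohol voluntarily for at least 6 weeks before mating, and in the other 4 the sire was a control. The dams had not been given alcohol. C57BL/6J is an inbred mouse strain and CD-1 an outbred stock. The title of the study speaks of growth, of placental adaptation and of their penetrance in offspring of alcohol-exposed sires, so the comparison asked here was how placental transcripts differed with the sire's exposure, in level and in spread between placentas. The labels do not say whether the placentas of a group came from separate litters, and p-values measure only the spread between these samples.

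Ribosomal RNA filled most of every library. The deposited counts summed to between 40.1 M and 65.9 M (M, mega) per library in the control sire group and between 58.4 M and 82.3 M in the alcohol-exposed sire group. mt-Rnr2, Rn18s and mt-Rnr1 together held 85.0% ± 4.93 (SD, n = 4) of the counts with a control sire and 88.9% ± 5.14 (SD, n = 4) with an alcohol-exposed sire. What remained was 4.36 to 14.2 M counts per control library and 2.97 to 8.76 M per alcohol-exposed sire library. The lowest value belonged to alcohol-exposed sire replicate 2, in which ribosomal RNA reached 96.4%. Among the other counts, the nuclear-retained RNA Malat1 took 4.57% ± 0.79 (SD, n = 4) with a control sire and 4.65% ± 0.44 (SD, n = 4) with an alcohol-exposed sire. The trophoblast cathepsin Ctsq took 1.09% ± 0.24 and 0.98% ± 0.22, the imprinted gene Peg3 0.64% ± 0.10 and 0.58% ± 0.10, and the placental lactogen Prl3b1 0.42% ± 0.06 and 0.46% ± 0.20 (SD, n = 4 in each group).

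The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were counted in all 8 libraries, as the male label requires. Ddx3y ranged from 57.2 to 141 CPM of the non-ribosomal counts. Xist, the long RNA transcribed from the inactive X chromosome of female cells, was also present. Its lowest value on that scale was 2.54 and its highest 90.05, or 789 counts, in alcohol-exposed sire replicate 3, followed by 36.0 in control sire replicate 4.

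Markers of the placental layers set the libraries of each group far apart. The junctional zone is the endocrine layer next to the maternal decidua, and the labyrinth is the layer of exchange. The difference between the mean log2 CPM of spongiotrophoblast genes, such as Tpbpa, and that of labyrinth syncytiotrophoblast genes, such as Gcm1 and Syna, ran from 0.92 to 3.72 in the control sire group and from 0.76 to 4.91 in the alcohol-exposed sire group. Its mean was 2.10 ± 1.34 (SD, n = 4) with a control sire and 2.58 ± 1.72 (SD, n = 4) with an alcohol-exposed sire, a difference of 0.48 (exact two-sided permutation p = 0.714). Maternal decidua markers ran from -1.64 to 1.29 and from -0.47 to 1.81 in the respective groups, and uterine natural killer cell markers from -1.24 to 1.59 and from -0.19 to 3.19. The first principal component, with 42.1% of the variance, followed the layer difference across the 8 libraries with Pearson r = 0.857 (exact permutation p = 0.00635, Benjamini-Hochberg adjusted p = 0.0159 over 8 relations) and Spearman rho = 0.786 (exact permutation p = 0.0279, adjusted p = 0.0559). The r was 0.962 without the 2 libraries farthest from the median, 0.994 within the control sire group and 0.795 within the alcohol-exposed sire group. That component did not separate the sire groups (exact permutation p = 0.343).

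**Figure D1:**
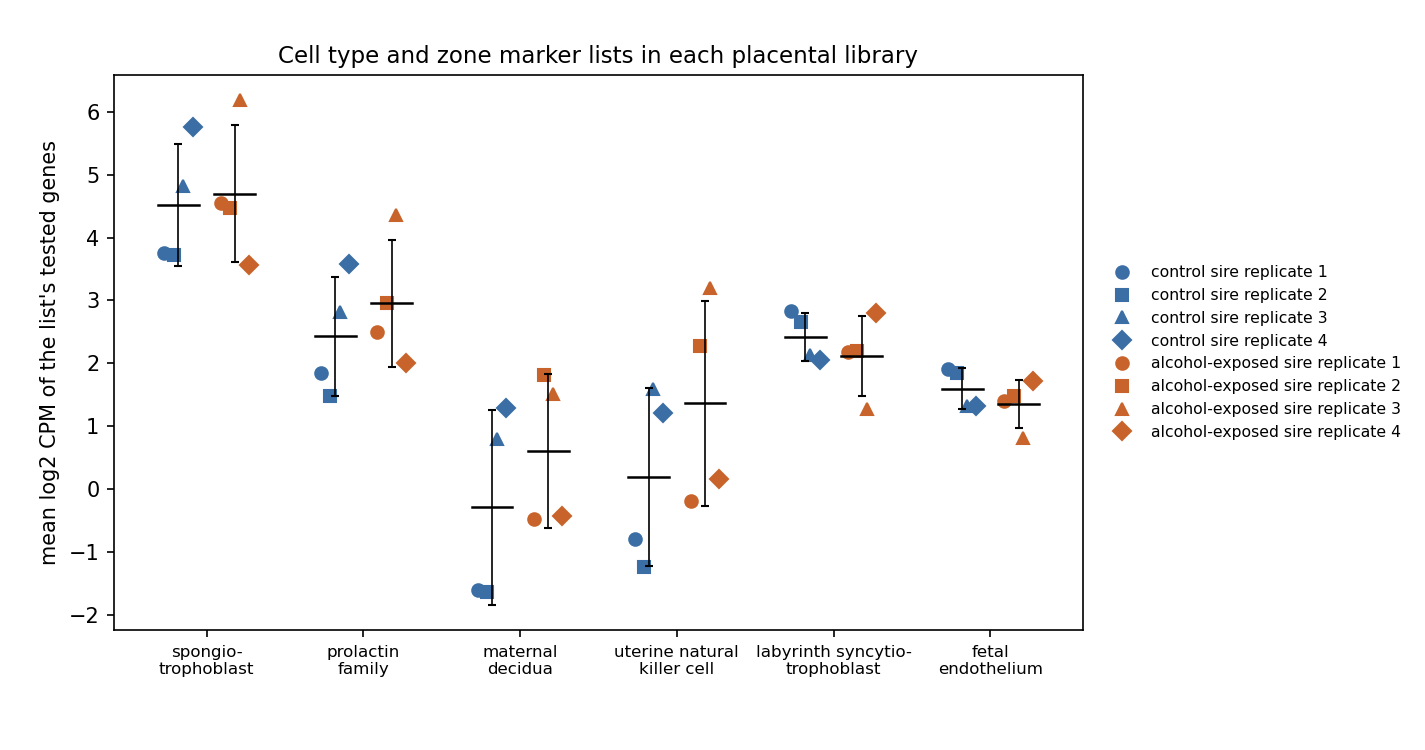
Mean log2 CPM of the tested genes of 6 marker lists (y axis) in each of the 8 libraries, with 1 symbol per library, a horizontal line at the group mean and a bar of 1 SD (n = 4 per group). Spongiotrophoblast values lie between 3.57 and 6.18, with the lowest and the highest both in the alcohol-exposed sire group, and alcohol-exposed sire replicate 3 is lowest for labyrinth syncytiotrophoblast markers at 1.28.

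No single gene passed the test between the sire groups. Of 14120 genes tested, 0 passed a Benjamini-Hochberg adjusted p of 0.05 in edgeR's quasi-likelihood test, where the lowest adjusted p was 0.996. At an unadjusted p under 0.05 there were 277 genes, 115 higher and 162 lower with an alcohol-exposed sire, against 706 expected by chance. limma-voom called 0 of the same genes, with 633 at an unadjusted p under 0.05, and DESeq2 called 0 of 39090 genes, low ones included, with 566 at an unadjusted p under 0.05. The groups did not overlap for 221 genes (1.57%), where chance gives 2.86%. In the real libraries, changes planted by simulation were called for 92 of 100 genes at 4-fold and for 41 of 100 at 2-fold. They were planted only in genes with a mean log2 CPM of at least 1 (6809 of those tested), so power for lower genes was not measured. All 200 changes were planted at once, which eases the Benjamini-Hochberg threshold. Power to call only a few changed genes would be lower and was not measured either. An edgeR likelihood ratio test called 1 gene, the uncharacterised 0610012D04Rik, at -4.66 ± 0.75 log2 (SE), and scaling by total counts alone called 1 gene, the connexin Gjb4, at 4.16 ± 0.80 log2 (SE). Both are named because they were the only calls of those fits, a choice made after their values were seen. Without a filter on low counts 80 genes passed, a count that 18 of 35 splits of the libraries reached.

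Among the better expressed genes nearest to a call on the higher side was Stk10, a serine/threonine kinase of lymphocytes, at 7.67 ± 2.52 CPM (SD, n = 4) with a control sire and 15.7 ± 6.81 CPM (SD, n = 4) with an alcohol-exposed sire. Its log2 fold change was 1.04 ± 0.33 (SE). Tomm7, a subunit of the mitochondrial import channel, stood at 2.07 ± 0.38 and 3.50 ± 0.54 CPM, a log2 difference of 0.75 ± 0.21 (SE). Mrps35, a mitochondrial ribosomal protein, differed by 0.62 ± 0.22 (SE) and Tbc1d8, of a family that acts on Rab GTPases, by 0.50 ± 0.17 (SE) on the log2 scale. Atp5e, the epsilon subunit of ATP synthase, differed by 0.67 ± 0.23 (SE) and the cytosolic ribosomal protein Rps9 by 0.57 ± 0.20 (SE). On the lower side, the transporter Abcc10 stood at 6.17 ± 2.64 CPM with a control sire and 2.89 ± 0.73 CPM with an alcohol-exposed sire, a log2 fold change of -1.09 ± 0.36 (SE). Abcb8, a mitochondrial transporter, differed by -0.83 ± 0.32 (SE) and Slc5a3, the sodium-dependent myo-inositol transporter, by -0.77 ± 0.30 (SE). Calcrl, the receptor for adrenomedullin in endothelium, differed by -0.69 ± 0.24 (SE), the lysosomal sialidase Neu1 by -0.53 ± 0.19 (SE) and Zfp229, of the zinc finger family, by -0.50 ± 0.18 (SE). All 12 had an adjusted p of 0.996 by edgeR's quasi-likelihood test. Without the filter on low counts Stk10 and Abcc10 passed the threshold, in a fit where 18 of 35 splits of the libraries gave at least the real 80 genes. Abcc10 in control sire replicate 4, at 2.23 CPM, lay below every alcohol-exposed sire library.

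**Figure D2:**
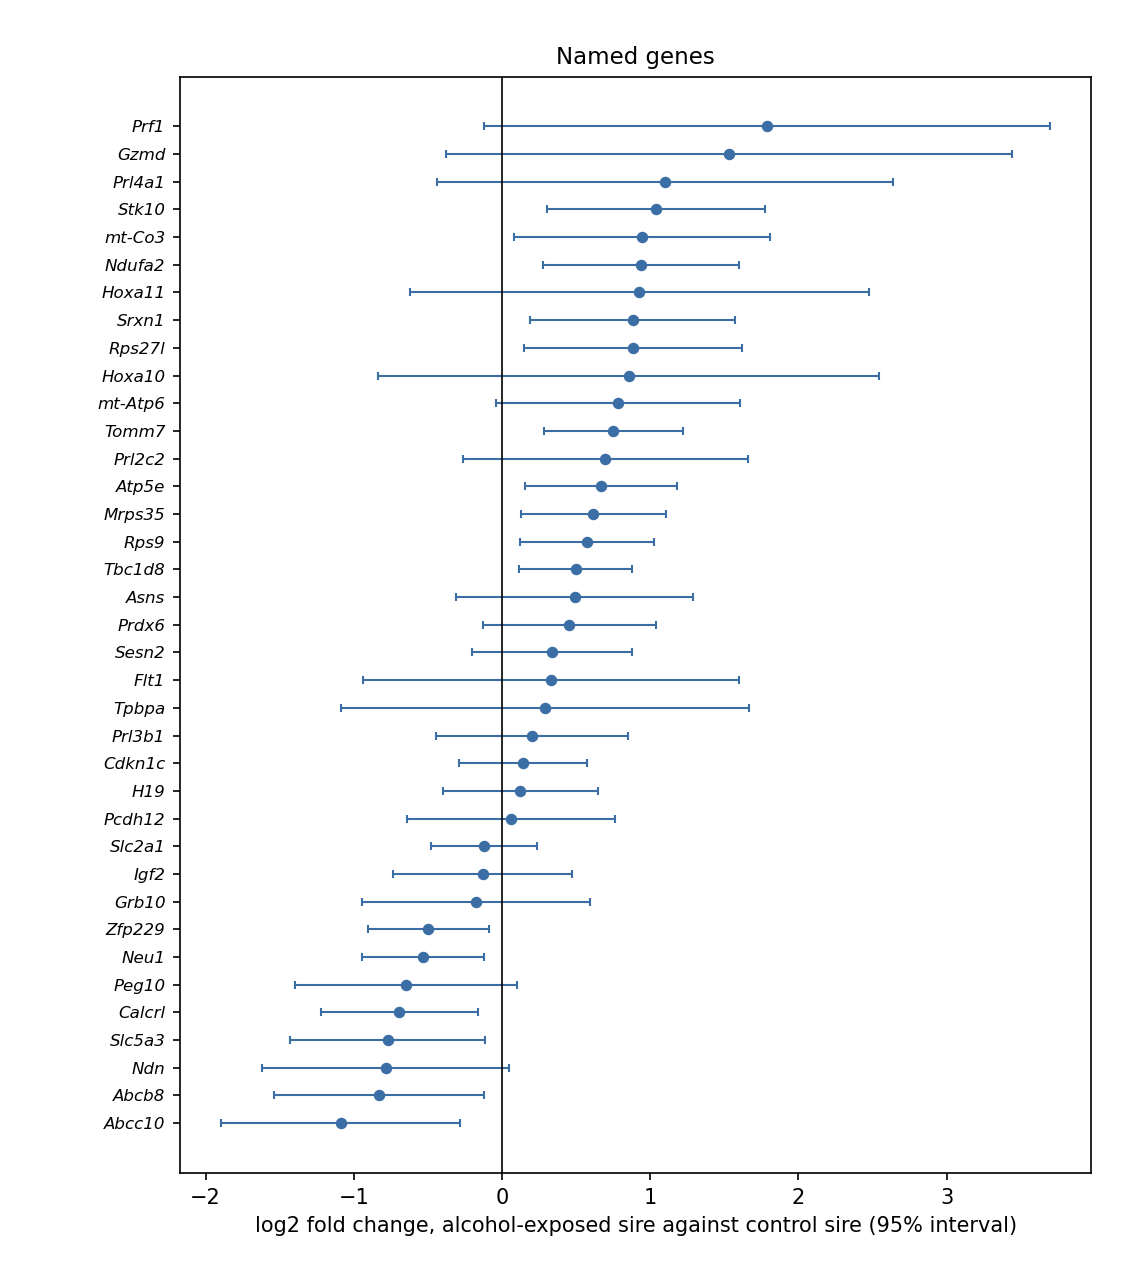
Log2 fold change of each named gene (x axis), alcohol-exposed sire against control sire, with bars for the 95% interval of edgeR's quasi-likelihood fit (n = 4 per group). Points run from -1.09 for Abcc10 to 1.79 for Prf1, none past the adjusted threshold, and scaling by total counts alone turns the sign for 8 of the 37 genes, or for 1 when taken relative to the median of all genes.

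None of the growth, imprinting and layer genes fixed in advance passed the test. H19, the maternally expressed long RNA of the Igf2 domain, stood at 279.8 ± 56.5 CPM (SD, n = 4) with a control sire and 305.0 ± 73.3 CPM (SD, n = 4) with an alcohol-exposed sire, a log2 fold change of 0.12 ± 0.24 (SE). Peg10, the paternally expressed gene needed for placental growth, stood at 699.4 ± 287.3 and 446.2 ± 127.1 CPM, with a log2 fold change of -0.65 (95% interval -1.40 to 0.10). The growth restrainers Cdkn1c and Grb10 differed by 0.14 ± 0.19 (SE) and -0.17 ± 0.35 (SE). Tpbpa, the spongiotrophoblast marker, differed by 0.29 ± 0.62 (SE) and Prl3b1 by 0.20 ± 0.29 (SE). Flt1, the soluble and membrane receptor for vascular endothelial growth factor, differed by 0.33 ± 0.57 (SE), the glycogen cell gene Pcdh12 by 0.06 ± 0.32 (SE) and the glucose transporter Slc2a1 by -0.12 ± 0.16 (SE). The signs of Flt1 (-0.46), Tpbpa (-0.39), Prl3b1 (-0.13), Pcdh12 (-0.39) and Grb10 (0.08) turned without alcohol-exposed sire replicate 3. Signs also turned without alcohol-exposed sire replicate 2 for H19 (-0.00), without control sire replicate 2 for Pcdh12 (-0.01) and Igf2 (0.14), and without control sire replicate 1 for Grb10 (0.01). For Slc2a1 the 95% interval ran from 0.72-fold to 1.18-fold. Phlda2, at 0 to 20 counts per library, and Hsd11b2, at 0 to 12, lay below the filter, so a difference in them was not detectable at this depth. Igf2 itself had 97 to 441 counts per library, 3.86 ± 1.35 CPM (SD, n = 4) with a control sire and 3.55 ± 0.86 CPM (SD, n = 4) with an alcohol-exposed sire. That level is uncertain, since in the GENCODE M21 annotation Igf2 overlaps Gm49394 on its own strand, which is listed at 0 counts in all 8 libraries, and Igf2os on the other strand.

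Cytosolic ribosomal protein genes, respiratory chain genes and genes of the mitochondrial genome stood higher with an alcohol-exposed sire as groups. Their calls rest on camera's preset correlation of 0.01 between genes, where camera itself estimated 0.788, 0.059 and 0.868 in that order. Exact two-sided permutation of the list means gave p = 0.2, 0.0571 and 0.2. Of 76 cytosolic ribosomal protein genes, 75 had a positive difference, with a mean of 0.50 ± 0.32 log2 (SE, n = 4 per group). Examples were Rps9 and Rps27l, the latter at 0.87 ± 0.29 CPM (SD, n = 4) with a control sire and 1.60 ± 0.58 CPM (SD, n = 4) with an alcohol-exposed sire. In limma's camera test with a preset correlation of 0.01 between genes the list had an adjusted p of 4.96e-23, and adjusted p = 0.694 with an estimated correlation. Among nuclear-encoded genes of oxidative phosphorylation, 65 of 79 were positive with a mean of 0.20 ± 0.07 log2 (SE), including Atp5e and Ndufa2, a subunit of complex I whose log2 difference was 0.94 ± 0.30 (SE). This list passed camera at an adjusted p of 7.70e-08, and had adjusted p = 0.535 with an estimated correlation. All 13 protein genes of the mitochondrial genome were positive with a mean of 0.59 ± 0.47 log2 (SE), among them mt-Co3 at 5.25 ± 1.21 CPM with a control sire and 10.2 ± 7.00 CPM with an alcohol-exposed sire, and mt-Atp6 with a log2 difference of 0.78 ± 0.37 (SE). Their camera adjusted p was 5.41e-06, with adjusted p = 0.694 with an estimated correlation. The highest mean of the mitochondrial list, 7.19, came from alcohol-exposed sire replicate 2, the library richest in ribosomal RNA, and the other 7 libraries lay between 5.06 and 5.69. mt-Co3 and mt-Atp6 have near-identical copies in the nuclear genome, so their counts are uncertain, as are those of ribosomal protein genes, which have many pseudogenes. With total counts alone the means of these 3 lists turned to -0.16, -0.44 and -0.07, while the median of all genes moved to -0.51. Without alcohol-exposed sire replicate 2 the mitochondrial mean was 0.18 ± 0.22 (SE), and without control sire replicate 1 the ribosomal protein mean was 0.31. All 3 calls held with any 1 library left out, but without alcohol-exposed sire replicates 2 and 3 together the ribosomal protein mean was 0.12 and its call ended, while the oxidative phosphorylation and mitochondrial calls held at smaller means of 0.12 and 0.36. Those libraries were the highest of their group in the ribosomal protein and oxidative phosphorylation lists, so smaller means there were largely fixed by that choice. The ribosomal protein list followed the difference between layer markers (Pearson r = 0.814, exact permutation p = 0.0151, adjusted p = 0.0241, and Spearman rho = 0.786, exact permutation p = 0.0279, adjusted p = 0.0559), and with the decidua score as a covariate its mean was 0.23 ± 0.14 (SE).

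Markers of uterine natural killer cells and of decidua, both maternal, were also called higher by camera with the preset correlation. So were genes of the prolactin family, hormones made by several trophoblast types and in part by decidua. Exact two-sided permutation of the list means gave p = 0.314, 0.400 and 0.486 in that order. The calls rest on the preset correlation of 0.01 between genes, where camera itself estimated 0.932, 0.525 and 0.599. All 7 uterine natural killer cell markers tested, of 14 fixed, were positive, with a mean of 1.17 ± 1.08 log2 (SE, n = 4 per group). Their camera adjusted p was 0.00538 (adjusted p = 0.694 with an estimated correlation). The 7 are the granzymes Gzmc, Gzmd, Gzme, Gzmf and Gzmg with Prf1 and Il2rb, which vary together, so their signs are not independent. Nkg7, Klrb1c, Klrk1, Klrd1, Ncr1, Gzma and Gzmb were not tested. Gzmd, a granzyme of natural killer cells, stood at 3.42 ± 3.06 CPM (SD, n = 4) with a control sire and 9.77 ± 9.64 CPM (SD, n = 4) with an alcohol-exposed sire, and Prf1, the pore-forming perforin, at 0.50 ± 0.43 and 1.63 ± 1.67 CPM. Of 11 maternal decidua markers 10 were positive, with a mean of 0.89 ± 0.99 log2 (SE) and a camera adjusted p of 0.0251 (adjusted p = 0.694 with an estimated correlation). The homeobox genes Hoxa10 and Hoxa11, which pattern the uterus, differed by 0.85 ± 0.76 (SE) and 0.93 ± 0.70 (SE). Of 22 placental prolactin family genes 20 were positive, with a mean of 0.53 ± 0.69 log2 (SE) and a camera adjusted p of 0.0143 (adjusted p = 0.694 with an estimated correlation). Prl4a1 differed by 1.10 ± 0.69 (SE) and Prl2c2, whose close paralogs can share its reads, by 0.70 ± 0.43 (SE). Both genes were highest in alcohol-exposed sire replicate 3. Prl4a1 stood there at 4.46 CPM against 1.16 to 1.43 in the rest of the group, and Prl2c2 at 25.9 against 6.79 to 10.9 CPM. Each of these 3 calls ended without control sire replicate 1 (means of 0.84, 0.40 and 0.33 in the order above), without control sire replicate 2 (0.69, 0.44 and 0.16) and without alcohol-exposed sire replicate 3 (0.56, 0.59 and 0.06). In the last case camera's direction for the prolactin family turned. Without control sire replicate 4 the decidua and prolactin means were larger, at 1.41 and 0.85, and without alcohol-exposed sire replicate 4 the prolactin mean was 0.80. Without alcohol-exposed sire replicate 2 the natural killer and decidua calls ended as well, at means of 0.88 and 0.52. Without alcohol-exposed sire replicates 2 and 3 together all 3 means turned, to -0.19 for natural killer cells, -0.12 for decidua and -0.21 for the prolactin family. Those libraries were the highest of their group in all 3 lists, so a fall of each mean was largely fixed by that choice. The lowest control libraries were not left out together. With total counts alone the prolactin family mean was -0.10, while the median of all genes moved to -0.51. The library highest in natural killer markers, alcohol-exposed sire replicate 3 at 3.19, was also the highest in Xist. Alcohol-exposed sire replicate 2, next at 2.27 and the highest of all in decidua markers at 1.81, had Xist at only 6.73 CPM of the non-ribosomal counts. That value rests on 20 counts.

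Antioxidant and stress genes were also on the higher side, and paternally expressed imprinted genes on the lower. Of 21 antioxidant genes 18 were positive, with a mean of 0.31 ± 0.21 log2 (SE, n = 4 per group) and a camera adjusted p of 0.00464 (adjusted p = 0.694 with an estimated correlation). With the decidua score as a covariate that mean was 0.13 ± 0.07 (SE, camera adjusted p = 0.0322). Srxn1, which repairs overoxidised peroxiredoxins, stood at 0.46 ± 0.10 CPM (SD, n = 4) with a control sire and 0.86 ± 0.21 CPM (SD, n = 4) with an alcohol-exposed sire, and Prdx6, itself a peroxiredoxin, at 2.69 ± 0.15 and 3.69 ± 1.37 CPM. Prdx6 was highest in alcohol-exposed sire replicate 1, at 5.52 CPM, and in replicate 3 of that group, at 2.20 CPM, it lay below every control. Of 21 genes of the endoplasmic reticulum and integrated stress response 18 were positive, with a mean of 0.14 ± 0.29 log2 (SE) and a camera adjusted p of 0.0472 (adjusted p = 0.694 with an estimated correlation). Asns, the asparagine synthetase, and Sesn2, a stress-induced sestrin, differed by 0.49 ± 0.36 (SE) and 0.34 ± 0.24 (SE). Of 26 paternally expressed imprinted genes 20 were negative, with a mean of -0.27 ± 0.19 log2 (SE) and a camera adjusted p of 0.0442 (adjusted p = 0.694 with an estimated correlation). Ndn stood at 0.82 ± 0.20 CPM with a control sire and 0.48 ± 0.19 CPM with an alcohol-exposed sire. The antioxidant call ended without alcohol-exposed sire replicate 3, at 0.23, as did the stress call at 0.01 and the imprinted call at -0.13. The stress and imprinted calls also ended without control sire replicate 1 (0.03 and -0.21), control sire replicate 2 (0.05 and -0.23) or alcohol-exposed sire replicate 2 (0.06 and -0.22), and the imprinted call without control sire replicate 4 (-0.30). The stress mean was larger without control sire replicate 3 (0.22) or 4 (0.30) and without alcohol-exposed sire replicate 1 (0.25) or 4 (0.27). It turned to -0.20 without alcohol-exposed sire replicates 2 and 3 together, where the antioxidant call ended too, at 0.03 ± 0.20 (SE), and the imprinted mean was -0.000103, and to -0.11 with the decidua score as a covariate. Replicates 2 and 3 were the highest of their group in the antioxidant and stress lists and its lowest in the imprinted list. The direction of those changes was thus largely fixed by leaving them out. The imprinted list ran against the difference between layer markers (Pearson r = -0.847, exact permutation p = 0.00796, adjusted p = 0.0159, and Spearman rho = -0.714, exact permutation p = 0.0576, adjusted p = 0.0921). With total counts alone the antioxidant and stress means were -0.33 and -0.51, the latter level with the median of all genes.

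Of the 33 lists tested, these 9 passed camera with the preset correlation, 8 higher and 1 lower. With an estimated correlation 0 lists passed, although without a filter on low counts oxidative phosphorylation did, at an adjusted p of 0.0465 and a mean of 0.17 ± 0.05 log2 (SE). Further, fry's directional test passed 0 at a lowest adjusted p of 0.694, and exact permutation of the list means over 70 assignments passed 0. The lowest exact p was 0.0571, for oxidative phosphorylation, where 0.0286 is the smallest the design allows. Adjusted over 33 lists, a single list at 0.0286 could not have reached 0.05, so the 0 by permutation was nearly fixed in advance. In no list did a member pass an adjusted p of 0.05 by edgeR's quasi-likelihood test over all genes, and 0 passed when adjusted over the list alone. Without a filter on low counts some members passed, such as Gzmd (1.54 log2), Gpx3 (1.54), Prl8a2 (1.47) and Tfpi2 (1.54). In that fit 18 of 35 splits gave at least the real 80 genes. Without alcohol-exposed sire replicates 2 and 3 together, 4 lists passed camera, of which 2 were among the 9.

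**Figure D3:**
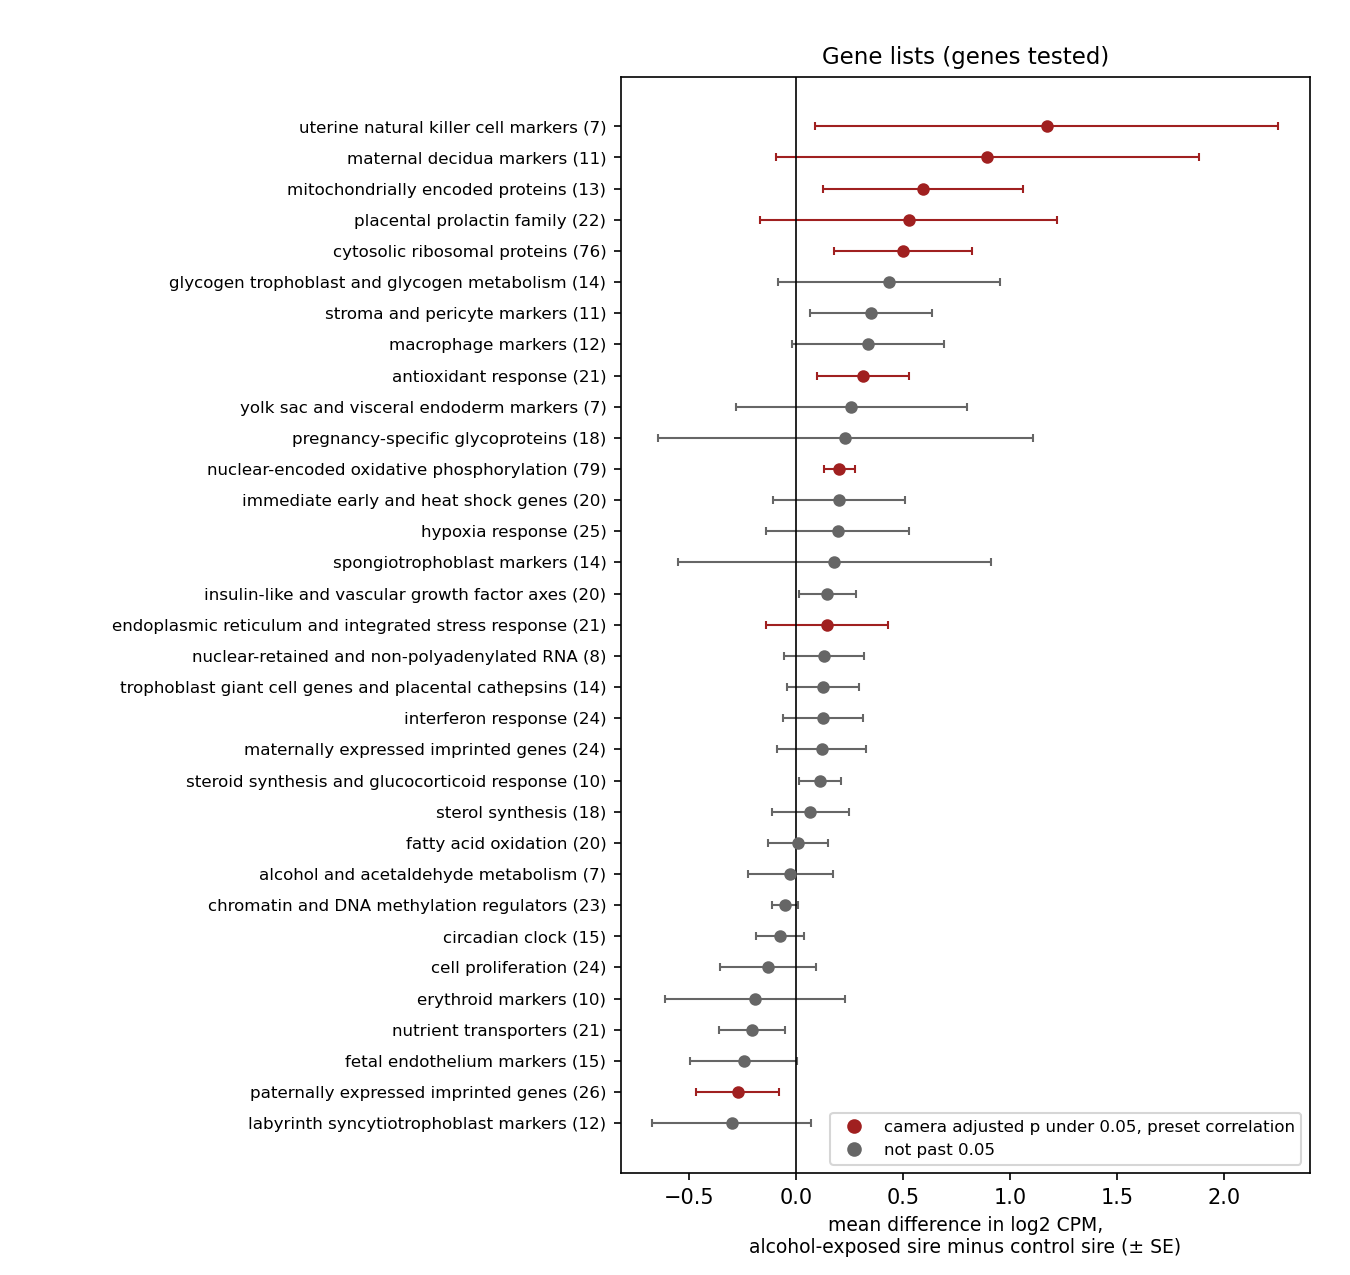
Mean difference in log2 CPM (x axis, alcohol-exposed sire minus control sire, bars of 1 SE, n = 4 per group) for the 33 gene lists tested, with the number of genes tested in brackets. The 9 lists past camera's adjusted p of 0.05 with a preset correlation are in red, 0 pass with an estimated one, and scaling by total counts alone turns the sign for 6 of the 9, or for 1 when taken relative to the median of all genes.

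The remaining cell type lists did not pass camera. Labyrinth syncytiotrophoblast and fetal endothelium markers had 9 of 12 and 11 of 15 members negative, with means of -0.30 ± 0.37 and -0.25 ± 0.25 log2 (SE, camera adjusted p = 0.101 for both). Nutrient transporters had 15 of 21 negative and a mean of -0.21 ± 0.15 (SE, adjusted p = 0.0555). Spongiotrophoblast markers had a mean of 0.18 ± 0.73 (SE, adjusted p = 0.336) and pregnancy-specific glycoproteins, a family of near-identical paralogs, 0.23 ± 0.88 (SE, adjusted p = 0.191). Glycogen trophoblast genes had 12 of 14 members positive and a mean of 0.43 ± 0.52 (SE, adjusted p = 0.0744), and giant cell genes with placental cathepsins 0.13 ± 0.17 (SE, adjusted p = 0.324). Stroma and pericyte markers had a mean of 0.35 ± 0.29 (SE, adjusted p = 0.0987), macrophage markers 0.34 ± 0.36 (SE, adjusted p = 0.0897), erythroid markers -0.19 ± 0.42 (SE, adjusted p = 0.652) and yolk sac markers 0.26 ± 0.54 (SE, adjusted p = 0.894). Without alcohol-exposed sire replicate 3 the signs turned for spongiotrophoblast markers (-0.32), pregnancy-specific glycoproteins (-0.31), erythroid markers (0.16) and yolk sac markers (-0.05), and the labyrinth mean was -0.01. The spongiotrophoblast and glycoprotein signs turned as well without control sire replicate 1 (-0.07 and -0.14) and control sire replicate 2 (-0.04 and -0.15). With alcohol-exposed sire replicates 2 and 3 both left out the signs turned for spongiotrophoblast markers (-0.45), glycoproteins (-0.48), glycogen trophoblast (-0.12), giant cells (-0.02), labyrinth (0.16), erythroid (0.29) and yolk sac markers (-0.20). Neutrophil markers were not tested because 4 members passed the filter.

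Nor did the remaining pathway lists pass camera. Hypoxia response genes had 19 of 25 members positive and a mean of 0.19 ± 0.34 log2 (SE, adjusted p = 0.0820), and interferon response genes 19 of 24 and 0.13 ± 0.18 (SE, adjusted p = 0.0820). Immediate early and heat shock genes had a mean of 0.20 ± 0.31 (SE, adjusted p = 0.148), insulin-like and vascular growth factor genes 0.15 ± 0.13 (SE, adjusted p = 0.354) and steroid and glucocorticoid genes 0.11 ± 0.10 (SE, adjusted p = 0.481). Cell proliferation genes had a mean of -0.13 ± 0.22 (SE, adjusted p = 0.324), sterol synthesis 0.07 ± 0.18 (SE, adjusted p = 0.583), fatty acid oxidation 0.01 ± 0.14 (SE, adjusted p = 0.703) and nuclear-retained RNA 0.13 ± 0.19 (SE, adjusted p = 0.324). Chromatin and DNA methylation regulators, with Dnmt1 and Tet1 among them, lay within -0.05 ± 0.06 (SE, adjusted p = 0.896). Genes of alcohol and acetaldehyde metabolism, such as Aldh2, had a mean of -0.03 ± 0.20 (SE, adjusted p = 0.894) and a median of 0.12, with camera's direction up. Maternally expressed imprinted genes had a mean of 0.12 ± 0.21 (SE, adjusted p = 0.896) and a median of -0.11, and circadian clock genes a mean of -0.08 ± 0.11 (SE, adjusted p = 0.652) and a median of 0.01. The signs of hypoxia (-0.07), sterol synthesis (-0.06) and proliferation (0.01) turned without alcohol-exposed sire replicate 3, and with replicate 2 of that group left out as well the means were -0.25, -0.13 and 0.07. In that same fit signs turned for immediate early genes (-0.12), growth factor genes (-0.00), nuclear-retained RNA (-0.11), maternally expressed imprinted genes (-0.10) and chromatin regulators (0.03), and fatty acid oxidation was at 0.19 ± 0.09 (SE), past camera at an adjusted p of 0.0223 but with 0 lists past an estimated correlation. Without alcohol-exposed sire replicate 2 they turned for maternally expressed imprinted genes (-0.10), chromatin regulators (0.03) and clock genes (0.01). The sign turned on leaving out any of 4 libraries for fatty acid oxidation (lowest -0.06, without alcohol-exposed sire replicate 4) and any of 6 for alcohol metabolism (highest 0.35, without alcohol-exposed sire replicate 1).

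The spread between placentas was compared as well. Over 6809 genes the SD between libraries was larger in the alcohol-exposed sire group by a median of 0.41 on the log2 scale, or 1.33-fold. Of the 35 ways to split the 8 libraries 4 against 4, 13 gave a ratio at least as far from 0 (exact two-sided permutation p = 0.371). Without alcohol-exposed sire replicate 3 the ratio was 0.04, without alcohol-exposed sire replicate 2 it was 0.25, and without control sire replicate 4 it was 0.65. Peg10 showed the opposite order in CPM, with an SD of 287.3 with a control sire and 127.1 with an alcohol-exposed sire. Its means were 699.4 and 446.2 CPM, so these SDs are not comparable with the log2 ratio, and it is a single gene.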

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

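The test of transcript length on alcohol-exposed sire replicate 2 was chosen only after the result had been seen. In groups of 4, a library was singled out where its gap to the nearest of the other libraries took up nearly the whole range of the group. Of 150 groups examined, 11 met this mark where chance gives about 7.5, or 1 in 20. Alcohol-exposed sire replicate 2 accounts for 4 of them. Its total of 82.3 M counts compares with 58.4 to 62.2 M in the rest of its group. Its mean log2 CPM of chromatin and DNA methylation regulators was 3.03, where the other 3 lay between 3.25 and 3.28, its Mrps35 level was 3.53 CPM against 2.41 to 2.51, and its mt-Co3 level 20.6 CPM against 5.86 to 7.45.

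The remaining ones are spread over other libraries. Macrophage markers stood at 0.11 log2 CPM in control sire replicate 4, against -1.03 to -0.98 in the other controls. Cell proliferation genes stood at -0.22 in control sire replicate 3, against 0.01 to 0.03. H19 was at 364.4 CPM in control sire replicate 2, against 247.7 to 255.6. Abcc10 was at 2.23 CPM in control sire replicate 4, against 7.13 to 7.74, and at 3.98 CPM in alcohol-exposed sire replicate 4, against 2.45 to 2.58. Tomm7 was at 2.71 CPM in alcohol-exposed sire replicate 4, against 3.67 to 3.83, and Prl4a1 at 4.46 CPM in alcohol-exposed sire replicate 3, against 1.16 to 1.43.

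Alcohol-exposed sire replicate 2 lies alone at one end of the second principal component, which holds 23.3% of the variance, with a gap to the next library of 53.6% of the component's range. Low depth as the whole cause is argued against: with all libraries thinned to the same non-ribosomal count, 105.4% of that gap was kept. Removal of a transcript length trend kept 100.1% of the gap, but that trend was fitted over all tested genes with a length, low ones included. Among genes with a mean log2 CPM of at least 1 the library's length slope of -0.461 was the lowest of the 8. A length trend therefore stays open. A poorer RNA or a less complete removal of ribosomal RNA may set this library apart and was not tested, and a biological difference of this placenta stays open as well.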

How the results depend on the processing

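The fits without ribosomal RNA genes, with halved counts, at equal depth, without alcohol-exposed sire replicates 2 and 3, and with length or GC trends removed were chosen after seeing the data, as was the count of genes past the threshold over splits. The count of 0 genes past an adjusted p of 0.05 (277 at an unadjusted p under 0.05 in edgeR) became 1 higher gene with total counts alone, 1 lower gene with the likelihood ratio test and 80 genes without a filter, 73 higher and 7 lower. It stayed 0 in every other fit of all genes, including DESeq2 (566 of 39090 genes at an unadjusted p under 0.05), limma-voom (633) and each library left out in turn. The 9 lists past camera became 17 without a filter, 4 with a surrogate variable, 4 without alcohol-exposed sire replicates 2 and 3, 5 with the length trend removed, 0 with an estimated correlation and 0 with fry, and 3 to 19 with a library left out, lowest without alcohol-exposed sire replicate 3 and highest without alcohol-exposed sire replicate 4. In between it was 4 without control sire replicate 1 or 2, 16 without 3 and 18 without 4, and 12 and 7 without alcohol-exposed sire replicates 1 and 2, the latter with 5 of the 9 shared. It was 12 with total counts alone (8 shared), 7 with limma-voom (4 shared), 6 with the decidua score (4 shared), 9 with the layer score (6 shared), 8 at a mean CPM of at least 1 (7 shared), 8 without haemoglobin and mitochondrial genes, 8 without ribosomal RNA genes, 8 with halved counts, 9 at equal depth, 7 with the GC trend removed, and 9 with median of ratios or upper quartile scaling. The spread ratio ran from 0.04 to 0.65 with a library left out and was 0.97 with total counts alone, with no call in any fit.

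With the decidua score as a covariate the spongiotrophoblast, pregnancy-specific glycoprotein and stress lists turned to -0.34, -0.41 and -0.11 (camera adjusted p = 0.0384, 0.00776 and 0.414). With the layer score the glycoproteins turned to -0.15 (camera adjusted p = 0.0496). In that fit stroma and pericyte markers, at 0.26, and nutrient transporters, at -0.15, also passed camera, each at an adjusted p of 0.0491. Without alcohol-exposed sire replicates 2 and 3 the means were -0.21 for the prolactin family, -0.12 for decidua, -0.19 for natural killer cells, -0.25 for hypoxia (past limma's camera at an adjusted p of 0.0354, as was fatty acid oxidation at 0.19 and an adjusted p of 0.0223), -0.20 for the stress list and -0.000103 for paternally expressed imprinted genes. The prolactin family mean ran from 0.0623 to 0.85 with a library left out, and camera's direction was down at the lowest, without alcohol-exposed sire replicate 3. The cause was not tested, beyond there being fewer libraries in those fits. Alcohol-exposed sire replicates 2 and 3 were the highest of their group in the prolactin, decidua, natural killer, hypoxia and stress lists. They were its lowest in the imprinted and fatty acid oxidation lists. The direction of these changes was thus largely fixed by leaving both out. The decidua list was not run against its own score. In each of these fits 0 lists passed with an estimated correlation. Without a filter 1 did, oxidative phosphorylation, at an adjusted p of 0.0465. Under the alternatives 86 of 855 list values changed sign, in 22 lists, and 38 of 882 values of named genes, in 17 genes. Values past the threshold in neither fit were compared by size, against 1 SE.

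No paired analysis was possible because the labels tie no library of a group to a library of the other. Replicate numbers here follow the order of the samples within a group. Since no split can give fewer than 0 genes, 35 of 35 splits reach the real count of 0, which says nothing about chance, and the highest other count was 1097. The split with 1097 sets control sire replicates 1 and 2 and alcohol-exposed sire replicates 1 and 4 against the rest. Those libraries lie on the negative side of the first principal component. They are also lowest in decidua markers, at -1.64 to -0.43 log2 CPM against 0.79 to 1.81 in the rest. The split thus points to a structure of the samples other than the sire. Without a filter, 18 of 35 splits gave at least the real 80 genes, with 2128 the highest other, so chance cannot be excluded for that count. Depth limits the low genes, with 2.97 M non-ribosomal counts in the shallowest library.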

Other observations

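The tests of tissue share and of sire treatment on the layer markers were chosen only after the result had been seen. Beyond the layer markers, only the hypoxia, paternally expressed imprinted and ribosomal protein lists were related to the layer difference. The other lists were not tested in this way, so the relation is not shown to be particular to these. Adjusted p-values cover only the 8 relations computed. Across the 8 libraries the hypoxia response list, with Pgk1, Egln3 and Bnip3 among its genes, followed the difference between spongiotrophoblast and labyrinth markers with Pearson r = 0.909 (exact permutation p = 0.00322, adjusted p = 0.0129 over 8 relations) and Spearman rho = 0.786 (exact permutation p = 0.0279, adjusted p = 0.0559). The r was 0.737 without the 2 libraries farthest from the median, 0.896 within the control sire group and 0.94 within the alcohol-exposed sire group. Paternally expressed imprinted genes went the other way, at r = -0.847 (exact permutation p = 0.00796, adjusted p = 0.0159) and rho = -0.714 (exact permutation p = 0.0576, adjusted p = 0.0921), with r = -0.809 without the 2 farthest libraries, -0.815 within controls and -0.938 within the alcohol-exposed sire group. Ribosomal protein genes had r = 0.814 (exact permutation p = 0.0151, adjusted p = 0.0241) and rho = 0.786 (exact permutation p = 0.0279, adjusted p = 0.0559), with r = 0.622 without the 2 farthest, 0.929 within controls and 0.826 within the alcohol-exposed sire group. Spongiotrophoblast and decidua markers varied together at r = 0.763 (exact permutation p = 0.0293, adjusted p = 0.0391) and rho = 0.595 (exact permutation p = 0.132, adjusted p = 0.151), with r = 0.702 without the 2 farthest, 0.963 and 0.599 within the groups.

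The layer markers ranged over 2.80 log2 within the control sire group and 4.15 within the alcohol-exposed sire group. Sequencing depth as the cause is argued against, since 102.4% of the range was kept with all libraries thinned to the same non-ribosomal count (r of the layer score with log2 depth = -0.208, exact permutation p = 0.621, adjusted p = 0.621, and rho = -0.238, exact permutation p = 0.582, adjusted p = 0.582, with r = -0.462 without the 2 farthest libraries, -0.608 and 0.148 within the groups). The sire's exposure does not account for the range within controls alone, and the group difference of 0.48 had an exact permutation p of 0.714. A candidate explanation is a varying share of junctional zone and decidua in the divided placentas: the mean of junctional zone, decidua and natural killer markers ran against that of labyrinth and endothelium at r = -0.890 (exact permutation p = 0.00186, adjusted p = 0.0129) and rho = -0.786 (exact permutation p = 0.0279, adjusted p = 0.0559), with r = -0.83 without the 2 farthest libraries, -0.980 and -0.833 within the groups. It stays open because Xist, which maternal cells carry, followed the decidua list only at r = 0.673 (exact permutation p = 0.0750, adjusted p = 0.0857) and rho = 0.643 (exact permutation p = 0.0962, adjusted p = 0.128), with r = 0.722 without the 2 farthest libraries, 0.983 and 0.697 within the groups. The library highest in decidua markers, alcohol-exposed sire replicate 2, had Xist at only 6.73 CPM of the non-ribosomal counts. That value rests on 20 counts in the shallowest library. Highest in decidua markers were replicates 3 and 4 of the control sire group and 2 and 3 of the alcohol-exposed sire group. Their Xist ran from 6.73 to 90.05, against 2.54 to 4.93 in the rest.

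Those marker lists were fixed before the tests, and they share genes. Of the 14 spongiotrophoblast markers tested 12 stand in another list, and of the 11 decidua markers 2 do. The 7 natural killer markers and the 12 labyrinth markers share 0 and 1. Among decidua genes the most abundant was Des, at 15.02 ± 16.5 CPM (SD, n = 4) with a control sire and 32.7 ± 33.1 CPM (SD, n = 4) with an alcohol-exposed sire.

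The higher level of ribosomal protein and oxidative phosphorylation genes invites technical explanations. By the longest annotated transcript of each gene, their median lengths were 1077 and 1003 bases, against 3351 bases over all tested genes. After a length trend or a GC trend was removed, the summed mean difference of both lists kept 97.8% and 109.8% of its size. Both lists stayed past camera's threshold. Those trends were fitted over all tested genes with a value, low genes included, and can miss a trend among better expressed genes. For genes with a mean log2 CPM of at least 1, length slopes ran from -0.132 to 0.442 in control libraries. In the alcohol-exposed sire group they ran from -0.461 to 0.126. The removal thus cannot decide on either trend. The layer score as a covariate left 80.6%, while the decidua score left 46.1% of the ribosomal protein and 77.6% of the oxidative phosphorylation difference, so that maternal tissue may carry part of the former. Chance cannot be excluded: 19 of the 35 splits gave at least the real count of 9 lists, and the highest other gave 20. The sire's exposure stays open beside these.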
